A study of Mus musculus with 12 samples.

How the data were processed

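RNA was measured in epididymal white fat, inguinal white fat and liver of male Mgl2-DTR mice and of male C57BL/6N wild-type mice of the same age. Per the labels' protocols, all mice were injected into the abdomen with 500 ng of diphtheria toxin per dose every 3 days, and tissues were taken on day 10. Tissue was homogenized in Trizol, and the RNA was treated with DNase I, purified on RNeasy columns, and amplified and labelled with biotin with the GeneChip WT PLUS kit for an Affymetrix mouse gene array. The deposited values are normalized log2 levels, 1 column per sample: the 12 columns have medians of 5.19 to 5.28, minima of 1.78 to 1.98 and maxima of 13.75 to 13.91, with no missing value. The submitters' processing notes name limma. The background correction, the normalization and the summarization are not given in the sources used here. The raw arrays were not used here.

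The 6 groups are the 3 tissues by the 2 genotypes, with 2 arrays each. Of the 41345 probes, 23521 carry exactly 1 gene symbol in the platform annotation, 1814 carry several and 16010 carry none that is listed. The probes with 1 symbol cover 22180 genes, of which 1082 have over 1 such probe, and the probe with the highest mean over the 12 arrays was used for each gene. A gene was tested if its mean over the 4 arrays of at least 1 tissue exceeded 5.71, the median of all values of the single-symbol probes, which left 12710 genes. Of the Entrez identifiers, 23328 were found in a RefSeq table, which changed 0 symbols.

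Each gene was fitted with limma 3.58.1 in R 4.3.3 on all 12 arrays, with 1 mean per group, which leaves 6 residual degrees of freedom. The variance was moderated with eBayes without trend, with 3.35 prior degrees of freedom. Tests were two-sided, p-values were adjusted by Benjamini and Hochberg over the genes tested, and a gene was called at an adjusted p under 0.05. The comparisons were Mgl2-DTR minus wild-type in each tissue, the average of these 3 changes, the inguinal minus the epididymal change, the liver change minus the mean change of both depots, and inguinal minus epididymal fat in wild-type mice. Only 2 arrays per group limit the precision of each value.

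Of 44 gene lists for pathways and cell types, 41 had at least 3 tested members. They were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists within a comparison and called at an adjusted p under 0.05. Camera with an estimated correlation was run beside it. Fry's directional test, which asks whether a list's genes move on balance in 1 direction, was run as well. With an estimated correlation the only calls within a tissue, in the difference between liver and fat, or in the average were those of the resident, alternatively activated macrophage list in inguinal fat, in that difference and in the average. The count adjusted over the list alone applies the same adjustment to the members of a list only. The lists, the models, the thresholds and most alternatives were chosen before the data were examined.

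The genes named follow a rule also chosen before the data were examined. In each tissue it takes Mgl2 and Retnla, then the 12 largest rises and 12 largest falls among called genes whose groups lie apart. Free places, up to 6 per direction, go to the smallest unadjusted p among genes with an absolute change of at least 0.58 and groups apart, which are given as values. Of each list it takes up to 4 members that passed, over all genes or adjusted over the list alone, or 3 members with the smallest p where none passed. In the other comparisons it takes the 8 largest changes in each direction, and predicted genes and small RNAs are skipped. Cx3cr1 in inguinal fat and the genes of the list test between depots were named after their values were seen.

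The alternatives were no filter on dim genes, a filter at the 75th percentile (7.57), all probes, the next brightest probe, quantile normalization again, cyclic loess within each tissue, eBayes with trend and robust, array weights, a replicate block, genotype and number as a random block, an adjusted p under 0.10, a change of at least 2-fold, the arrays of 1 tissue or of both fat depots alone, and leaving out each array in turn. Where an array left out leaves an arm with 1 sample, that lone sample is assumed to vary like the other groups. After the data were seen, 4 more were added, namely leaving out the 2 muscle-bearing inguinal arrays, the mean of the muscle genes as a covariate, leaving out the 2 epididymal arrays that stood apart, and a crossed block in inguinal fat. The model was tested on simulated data of the same size, where most changes of 2 or more on the log2 scale were recovered. Changes of 1 were recovered in 52% to 74% of genes, and 12 of 196 epididymal calls were false. The simulated noise was independent between genes and alike in all arrays, unlike the real data, and held no muscle or duct tissue.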

Results

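The data were RNA levels on mouse gene arrays from male mice that had all received diphtheria toxin. Mgl2-DTR mice carry the diphtheria toxin receptor under the control of Mgl2, the gene for the lectin CD301b, so that the toxin kills CD301b-positive mononuclear phagocytes, while wild-type mice keep them. Epididymal white fat, inguinal white fat and liver were taken on day 10, with 2 arrays for each genotype in each tissue, 12 in all. Each array held 41345 probes, and its median log2 level lay between 5.19 and 5.28. Pearson's r between arrays, across all probes, was 0.974 to 0.983 within a group and 0.870 to 0.895 between fat and liver. Between the genotypes of a tissue it was 0.962 to 0.988, so arrays of a group were not always more alike than arrays of both genotypes. Only 2 arrays per group limit the precision of every value. The labels do not say that replicates are separate animals beyond the word mouse, so the p-values measure the spread between these samples. That spread is 1 estimate per gene shared by the 6 groups, not the spread within a tissue. Across genes, the SD of replicate 2 minus replicate 1 was 0.51 and 0.55 in wild-type and Mgl2-DTR epididymal fat. It was 0.35 and 0.35 in inguinal fat, and 0.32 and 0.30 in liver. The shared estimate can thus be too small for epididymal fat and too large for liver. Changes are Mgl2-DTR minus wild-type on the log2 scale with their standard error (SE), and levels are means ± SD of n = 2 arrays. Where a level lay under 5.71, the filter level for dim genes, the probe may sit at background, so the log2 change is limited by that floor and is not an exact size.

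The first comparison asks what changed in epididymal fat when CD301b-positive cells were depleted. Mgl2 was at 4.22 ± 0.046 in Mgl2-DTR against 7.34 ± 0.17 in wild-type fat, and no fold is given for it, since the lower level lay under the filter level. Retnla, which encodes a protein secreted by alternatively activated macrophages, fell by 3.32 (SE 0.39; limma adjusted p = 0.0371), from 10.53 ± 0.13 to 7.21 ± 0.97. Cd209g, a C-type lectin of the DC-SIGN family, fell by 2.63 (SE 0.31; adjusted p = 0.0371), to a level of 3.82 that lay under it too, and Fcrls, an Fc receptor-like gene of tissue macrophages, fell by 1.71 (SE 0.20; adjusted p = 0.0371). Mgl2 itself fell by 3.12 (SE 0.24; adjusted p = 0.00376). Each of these 4 genes was lower in both Mgl2-DTR arrays than in both wild-type arrays. No other gene of the 12710 tested passed, and none rose. These 4 genes kept their direction in every alternative run for single genes. The balance of all calls hung on the arrays kept, since most were higher when Mgl2-DTR replicate 1 was left out. The only Mgl2-DTR array then left is the one high in genes of the epididymal duct, described below.

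Of the 18 tested genes of resident, alternatively activated macrophages, 17 were lower, 2 fell over all genes and 11 fell adjusted over the list alone, among them Ccl8 (-1.55, SE 0.30) and F13a1 (-1.35, SE 0.38). The list's adjusted p was 6.03e-15 by camera, and adjusted p = 0.0745 with an estimated correlation. Of 18 pan-macrophage genes, 0 fell over all genes and 8 fell adjusted over the list alone, including Csf1r, the receptor for a macrophage growth factor (-1.53, SE 0.35), the Fc receptor Fcgr3 (-1.29, SE 0.37), Adgre1 (-1.24, SE 0.42) and the complement gene C1qc (-1.20, SE 0.17). That list had an adjusted p of 2.34e-14 by camera, and adjusted p = 0.503 with an estimated correlation. Of the 7 tested genes of antigen presentation on MHC class II, 0 fell over all genes and 4 fell adjusted over the list alone, H2-Ab1 by 1.18 (SE 0.20), H2-Eb1 by 1.11 (SE 0.21), H2-DMa by 1.10 (SE 0.27) and H2-Aa by 1.03 (SE 0.20). Its camera adjusted p was 4.53e-07, and adjusted p = 0.381 with an estimated correlation. Of the 14 genes of CD301b-positive phagocytes and type 2 conventional dendritic cells, 1 fell over all genes, and adjusted over the list alone 6 fell and 1 rose. Mgl2 led the falls, followed by Clec4a3 (-1.80, SE 0.46), Itgax (-1.67, SE 0.51) and Clec4a1 (-1.59, SE 0.51), with a camera adjusted p of 0.00106 and adjusted p = 0.539 with an estimated correlation. Of 9 Kupffer cell genes, 0 fell over all genes and 1 fell adjusted over the list alone, Vsig4, a complement receptor of resident macrophages (-1.87, SE 0.26). Vsig4 fell from 6.17 in wild-type fat to under the filter level. The list had a camera adjusted p of 0.000623, and adjusted p = 0.381 with an estimated correlation. Its call was lost without wild-type replicate 2, at a median of -0.18.

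The macrophage, lipid and growth-related genes of epididymal fat also differed between the arrays of a group. Wild-type replicate 1 had a mean level of 10.62 for pan-macrophage genes, against 9.69 in wild-type replicate 2, 9.35 in Mgl2-DTR replicate 1 and 9.04 in Mgl2-DTR replicate 2. In the same order, the mean of 12 genes of lipid-associated macrophages was 11.38, 10.09, 10.21 and 9.89. None of these 12 passed, with Mmp12 at -1.47, Trem2 at -1.29 and Lipa at -0.96. The list had a camera adjusted p of 0.000112, and adjusted p = 0.719 with an estimated correlation. The 21 cell cycle genes averaged 8.12, 6.55, 7.06 and 6.79, and none passed (Nusap1 -0.75, Mcm5 -0.65, Cdk1 -0.65; camera adjusted p = 0.00133; adjusted p = 0.799 with an estimated correlation). Without wild-type replicate 1 the list median turned from -0.42 to 0.41 for cell cycle genes, and for lipid-associated macrophage genes it was -0.034 with the test turned upward.

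Among the other groups of epididymal fat, 16 of 17 interferon-stimulated genes were higher and none passed, with Usp18 at 0.77, Irf7 at 0.54 and Stat2 at 0.53. The list had a camera adjusted p of 7.51e-05, and adjusted p = 0.719 with an estimated correlation. Its mean was 8.22 in Mgl2-DTR replicate 1 and 7.30 to 7.65 in the other 3 arrays, and its adjusted p was 0.924 without Mgl2-DTR replicate 1. All 15 endothelial genes missed the threshold (Tie1 0.47, Tek 0.42, Flt1 0.41; camera adjusted p = 0.0325; adjusted p = 0.799 with an estimated correlation), and without wild-type replicate 1 the direction of their test turned, at a median of -0.027, while the adjusted p was 0.957 without Mgl2-DTR replicate 1. All 14 fibro-adipogenic progenitor genes missed it too (Mgp 0.61, Dpp4 0.48, Cd34 0.29; camera adjusted p = 0.0443; adjusted p = 0.719 with an estimated correlation). Their call was lost without wild-type replicate 1 (adjusted p = 0.602) or Mgl2-DTR replicate 1 (adjusted p = 0.748), and at 0.0504 to 0.0576 without an Mgl2-DTR inguinal or a wild-type liver array. The 15 hepatocyte genes had a median of -0.45 and none passed (Tdo2 -0.998, Fabp1 -0.94, Apob -0.88; camera adjusted p = 0.000775; adjusted p = 0.719 with an estimated correlation). Their mean was 6.53 in wild-type replicate 2 and 5.38 to 5.49 in the other 3 arrays, and the median was 0.061 without that array.

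Genes of the epididymal duct were high in a single epididymal fat array. The 6 tested genes of epididymis and testis averaged 11.57 in Mgl2-DTR replicate 2 and 5.43 to 5.60 in the other 3 arrays. Over all genes 0 of the 6 passed, and adjusted over the list alone 1 fell, Odf1, a sperm tail gene (-0.48, SE 0.14), although its dimmer probe gave 0.81 and the probe used averaged 11.92 over all 12 arrays, liver included. The list had a camera adjusted p of 0.032, adjusted p = 0.719 with an estimated correlation, and an adjusted p of 0.844 without Mgl2-DTR replicate 2 and 0.371 without wild-type replicate 2. All 7 epithelial genes were higher and none passed (Epcam 2.40, Cldn3 1.31, Krt8 0.70; camera adjusted p = 7.51e-05; adjusted p = 0.667 with an estimated correlation). Epcam stood at 8.53 in Mgl2-DTR replicate 2 and at 5.62 in replicate 1, and the epithelial list's adjusted p was 0.310 without replicate 2.

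Further epididymal genes set the groups apart without passing over all genes. Lower were Cd33 at -1.74 (adjusted p = 0.0764), Abca9 at -1.31, the complement gene C1qa at -1.12 and Gbgt1 at -0.97. Higher were Dao at 1.43, Dcdc2a at 1.40, Erdr1 at 1.22, Cabcoco1 at 0.99, Tm4sf4 at 0.91 and Myb at 0.85 (adjusted p = 0.198), although a dimmer probe of Myb gave -0.016. By limma 887 genes had an unadjusted p under 0.05, 445 of them higher, and the groups lay apart for 29.5% of genes against 33.3% by chance. The 4 calls became 0 without Mgl2-DTR replicate 2 (454 genes at an unadjusted p under 0.05), 10 without wild-type replicate 1, 249 without Mgl2-DTR replicate 1, 763 without wild-type replicate 2, and 1 or 2 without any array of another tissue. With both wild-type replicate 1 and Mgl2-DTR replicate 2 left out there were 5 calls, of which only Cd209g was shared, and with the epididymal arrays alone or a stricter filter on dim genes there were 0 (285 and 484 at an unadjusted p under 0.05). The changes themselves kept their direction in the 13 alternatives run for single genes, with Mgl2 between -3.25 and -2.97, Fcrls between -1.85 and -1.57, Cd209g between -3.22 and -2.08 and Retnla between -4.00 and -2.54.

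**Figure D1:**
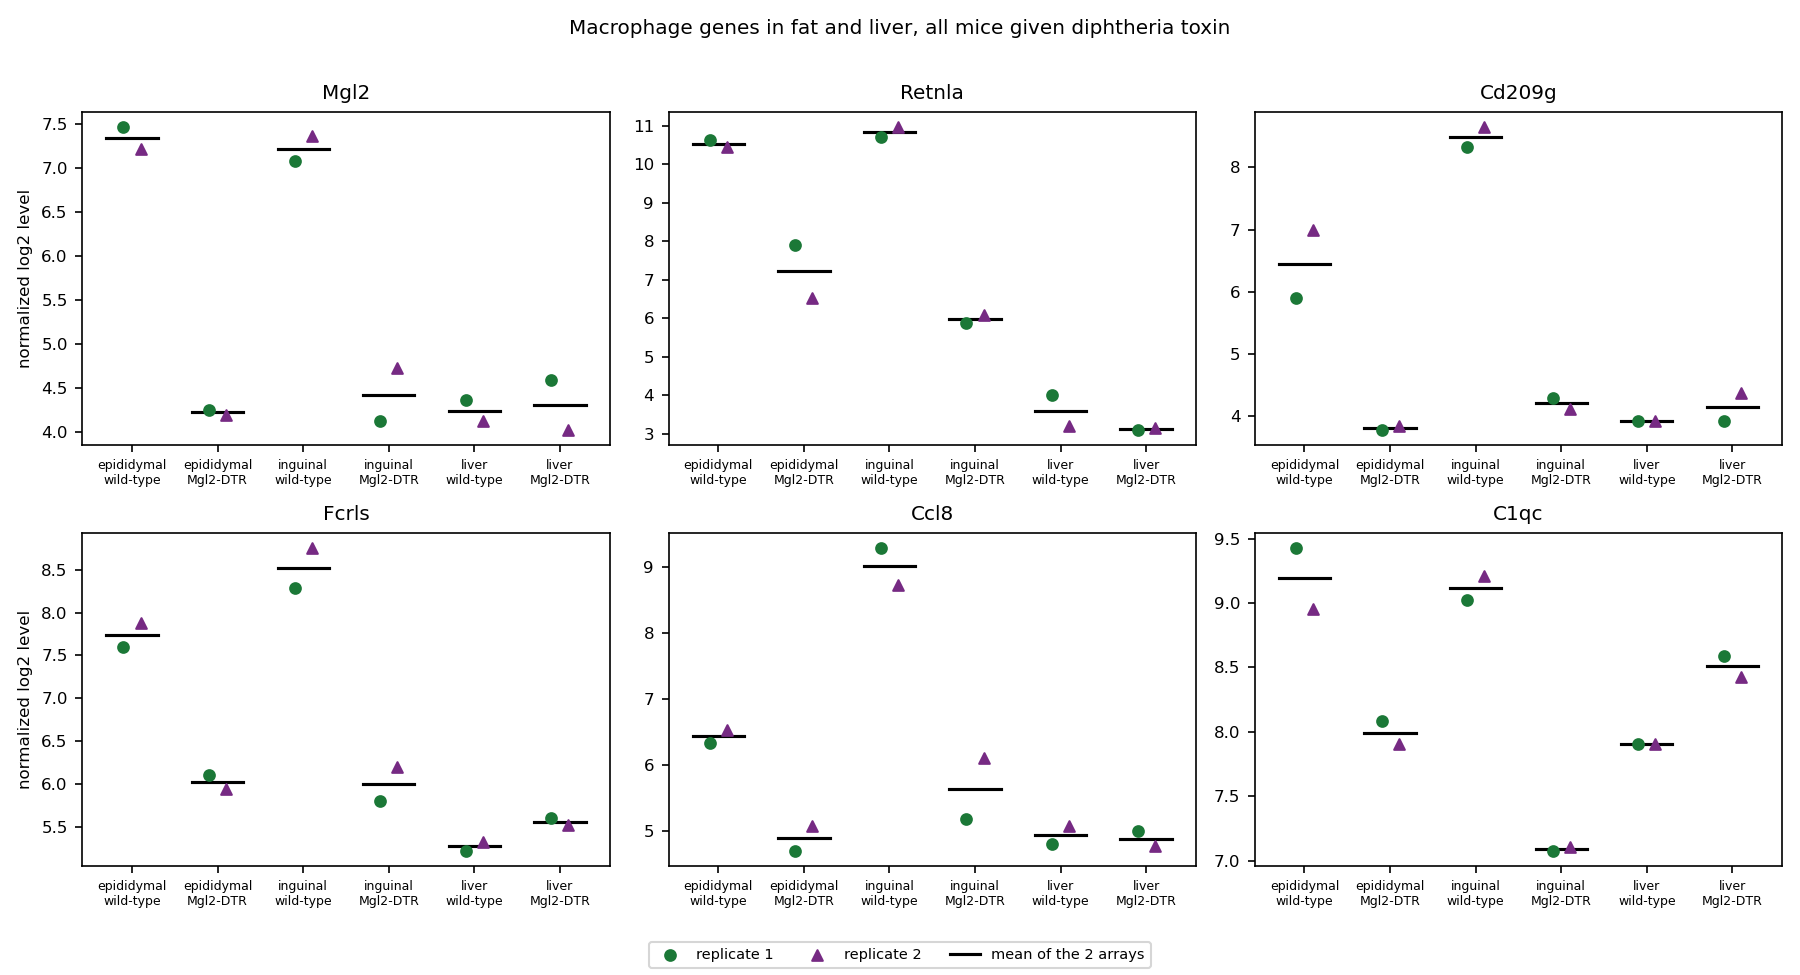
Normalized log2 level (y axis) of Mgl2, Retnla, Cd209g, Fcrls, Ccl8 and C1qc in the 6 groups (x axis), with green circles for replicate 1, purple triangles for replicate 2 and a black line for the mean of the 2 arrays. Mgl2 stood at 7.34 in wild-type and 4.22 in Mgl2-DTR epididymal fat, at 7.22 and 4.42 in inguinal fat, and at 4.24 and 4.31 in liver.

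The same comparison was made in inguinal fat. Mgl2 fell by 2.80 (SE 0.24; adjusted p = 0.00199), to a level of 4.42 that again lay under the filter level. Retnla was 29.0-fold lower (-4.86, SE 0.39; adjusted p = 0.00179), at 5.99 ± 0.15 against 10.84 ± 0.17, and Cd209g fell by 4.28 (SE 0.31; adjusted p = 0.00179), to 4.21 ± 0.14, under the filter level. Ccl8, a chemokine of resident macrophages, fell by 3.37 (SE 0.30; adjusted p = 0.00204), and Fcrls fell by 2.51 (SE 0.20; adjusted p = 0.00179). In all, 24 genes fell and 1 rose, Itgb8, an integrin that activates TGF-beta (1.78, SE 0.20; adjusted p = 0.00738). Of the falls, 8 ended under the filter level, those of Mgl2, Cd209g, Ccl8, Clec10a, Lyz1, Ms4a14, Aoah and Slc40a1, and Itgb8 rose from under it, so the sizes of these 9 changes are limited by the floor.

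Of the 18 tested genes of resident, alternatively activated macrophages, 4 fell over all genes, and adjusted over the list alone 13 fell and 1 rose. Besides Retnla, Cd209g and Ccl8, the scavenger receptor Cd163 fell adjusted over the list alone (-2.52, SE 0.43). The camera adjusted p was 1.30e-31, and adjusted p = 0.0101 with an estimated correlation. Of 18 pan-macrophage genes, 3 fell over all genes, the complement genes C1qc (-2.03, SE 0.17), C1qb (-1.94, SE 0.21) and C1qa (-1.92, SE 0.18), and adjusted over the list alone 8 fell, Csf1r among them (-2.10, SE 0.35), and 1 rose, Cx3cr1 (0.48, SE 0.13). The camera adjusted p was 1.25e-20, and adjusted p = 0.260 with an estimated correlation. Of 7 MHC class II genes, 3 fell over all genes and 5 adjusted over the list alone, with H2-Ab1 at -1.85, H2-Aa and H2-Eb1 at -1.77, and H2-DMa at -0.997 (camera adjusted p = 3.21e-15; adjusted p = 0.106 with an estimated correlation). Of 14 genes of CD301b-positive phagocytes and type 2 dendritic cells, 2 fell over all genes, Mgl2 and its close relative Clec10a (-2.85, SE 0.41), and 4 fell adjusted over the list alone, with Clec4a1 at -1.78 and Clec4a3 at -1.63. That list had a camera adjusted p of 7.99e-10, and adjusted p = 0.111 with an estimated correlation.

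Other genes that fell in inguinal fat were Lyz1, a lysozyme (-3.00, SE 0.35; adjusted p = 0.0082), Ms4a14 (-2.69, SE 0.39), Aoah, an enzyme that inactivates endotoxin (-2.47, SE 0.26), Folr2, a folate receptor of resident macrophages (-2.43, SE 0.24), and Wfdc17 (-2.15, SE 0.28), with Lyz1 at 5.24, Ms4a14 at 4.78 and Aoah at 5.54 in Mgl2-DTR fat, under the filter level. Cidea, a lipid droplet protein of brown and beige adipocytes, fell by 1.56 (SE 0.19; adjusted p = 0.00996). Of 13 brown and beige genes, 1 fell over all genes and 2 fell adjusted over the list alone, Cidea and Cox8b (-1.15, SE 0.20), while the list itself missed the threshold (camera adjusted p = 0.101). Of 9 Kupffer cell genes, 1 fell over all genes, the iron exporter Slc40a1 (-1.67, SE 0.23). Adjusted over the list alone 2 fell, with Vsig4 at -0.88, and 1 rose, Clec4f at 0.52, both under the filter level in both genotypes (camera adjusted p = 0.00897; adjusted p = 0.282 with an estimated correlation; adjusted p = 0.0539 without Mgl2-DTR replicate 1). Of 12 genes of lipid-associated macrophages, 0 fell over all genes and 2 fell adjusted over the list alone, Atp6v0d2 (-2.36, SE 0.61) and Mmp12 (-2.19, SE 0.52; camera adjusted p = 2.86e-05; adjusted p = 0.502 with an estimated correlation).

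Matrix, mast cell and interferon genes formed further groups in inguinal fat. Of 21 extracellular matrix genes, 0 fell over all genes and 3 fell adjusted over the list alone, the fibrillar collagens Col1a1 (-1.09, SE 0.23), Col1a2 (-0.93, SE 0.18) and Col3a1 (-0.85, SE 0.24), with a camera adjusted p of 3.87e-06 and adjusted p = 0.282 with an estimated correlation. Of 7 genes of type 2 immunity, 0 fell over all genes and 3 fell adjusted over the list alone, the mast cell proteases Mcpt4 (-1.46), Tpsb2 (-1.27) and Cpa3 (-1.26; camera adjusted p = 0.00754; adjusted p = 0.384 with an estimated correlation). This call was lost without Mgl2-DTR replicate 1 (adjusted p = 0.141). Of 17 interferon-stimulated genes, 16 were higher, 0 rose over all genes and 2 rose adjusted over the list alone, Cxcl10 (1.04, SE 0.26) and Stat2 (0.77, SE 0.16; camera adjusted p = 7.25e-05; adjusted p = 0.689 with an estimated correlation). None of 9 T and NK cell genes passed (Cd8b1 -0.52, Nkg7 -0.51, Cd4 -0.42; camera adjusted p = 0.000176; adjusted p = 0.282 with an estimated correlation), and the call was lost without wild-type replicate 1 (adjusted p = 0.161). None of 20 genes of fatty acid and triglyceride synthesis passed (Me1 -0.43, Acly -0.35, Slc25a1 -0.26; camera adjusted p = 0.0237; adjusted p = 0.832 with an estimated correlation), and the adjusted p was 0.974 without wild-type replicate 1 and 0.740 without Mgl2-DTR replicate 2. None of 15 hepatocyte genes passed (Tdo2 -0.81, from 4.71 and so under the filter level, Fabp1 -0.47, Serpina1a 0.36; camera adjusted p = 0.0474; adjusted p = 0.832 with an estimated correlation). Their call was lost without wild-type replicate 2 (adjusted p = 0.850) or Mgl2-DTR replicate 1 (adjusted p = 0.273), and at 0.0525 to 0.0654 without an Mgl2-DTR epididymal or a wild-type liver array. Genes of insulin signalling missed the threshold as a list, and 1 of 21 rose adjusted over the list alone, Irs2, an adaptor of the insulin receptor (1.23, SE 0.27).

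Skeletal muscle genes marked 1 array of each genotype in inguinal fat. Their mean was 10.18 in wild-type replicate 2 and 9.88 in Mgl2-DTR replicate 1, against 6.87 in wild-type replicate 1 and 6.84 in Mgl2-DTR replicate 2. The muscle gene Tnni2 stood at 10.01 and 8.53 in the first pair and at 6.27 and 6.16 in the other. With the mean of the muscle genes as a covariate 27 genes were called, 23 of the 25 among them. With both muscle-bearing arrays left out, which leaves 1 array per genotype, limma called 0 genes, with 479 at an unadjusted p under 0.05. The changes of Retnla, Cd209g and Mgl2 were then -4.63, -4.21 and -2.35. The pan-macrophage median was then -0.52, a smaller fall than with all arrays.

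Genes that were higher in inguinal fat without passing were Tenm3 at 1.13 and Cyp4f14 at 0.81 (both adjusted p = 0.0854), Gal3st2b at 0.93, Gadd45b at 0.83, Ecscr at 0.71 and Ooep at 0.64. By limma 881 genes had an unadjusted p under 0.05, 606 of them higher, and the median change of all genes was 0.10, so that small changes read relative to that shift. The groups lay apart for 46.9% of genes, against 33.3% by chance. A shift of all genes can by itself set groups apart, so this excess is no measure of a response. With cyclic loess within each tissue the median change was 0.0044. By limma 695 genes then had an unadjusted p under 0.05, and all 25 calls were kept. The 25 calls became 6 without wild-type replicate 2, 16 without Mgl2-DTR replicate 1, and 38 without either wild-type array of epididymal fat. They became 44 without the 2 epididymal arrays that stood apart, 9 with the fat arrays alone, and 4 with the inguinal arrays alone. Of the named calls, those of Mgl2, Retnla, Cd209g, Ccl8, Fcrls and C1qc held whichever 1 of the 4 inguinal arrays was left out, and those of Clec10a, Ms4a14 and Slc40a1 were lost each time (adjusted p = 0.0868 to 0.358). Lost without wild-type replicate 2 were Aoah, Folr2, C1qa and C1qb (0.0517 to 0.0721), and lost without either wild-type array were Wfdc17 and H2-Aa (0.0714 to 0.143). Itgb8 was lost without wild-type replicate 2 or Mgl2-DTR replicate 1 (at least 0.0783), Lyz1, H2-Ab1 and H2-Eb1 without either wild-type array or Mgl2-DTR replicate 1 (0.0545 to 0.101), and Cidea without either wild-type array or Mgl2-DTR replicate 2 (0.0666 to 0.101).

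**Figure D2:**
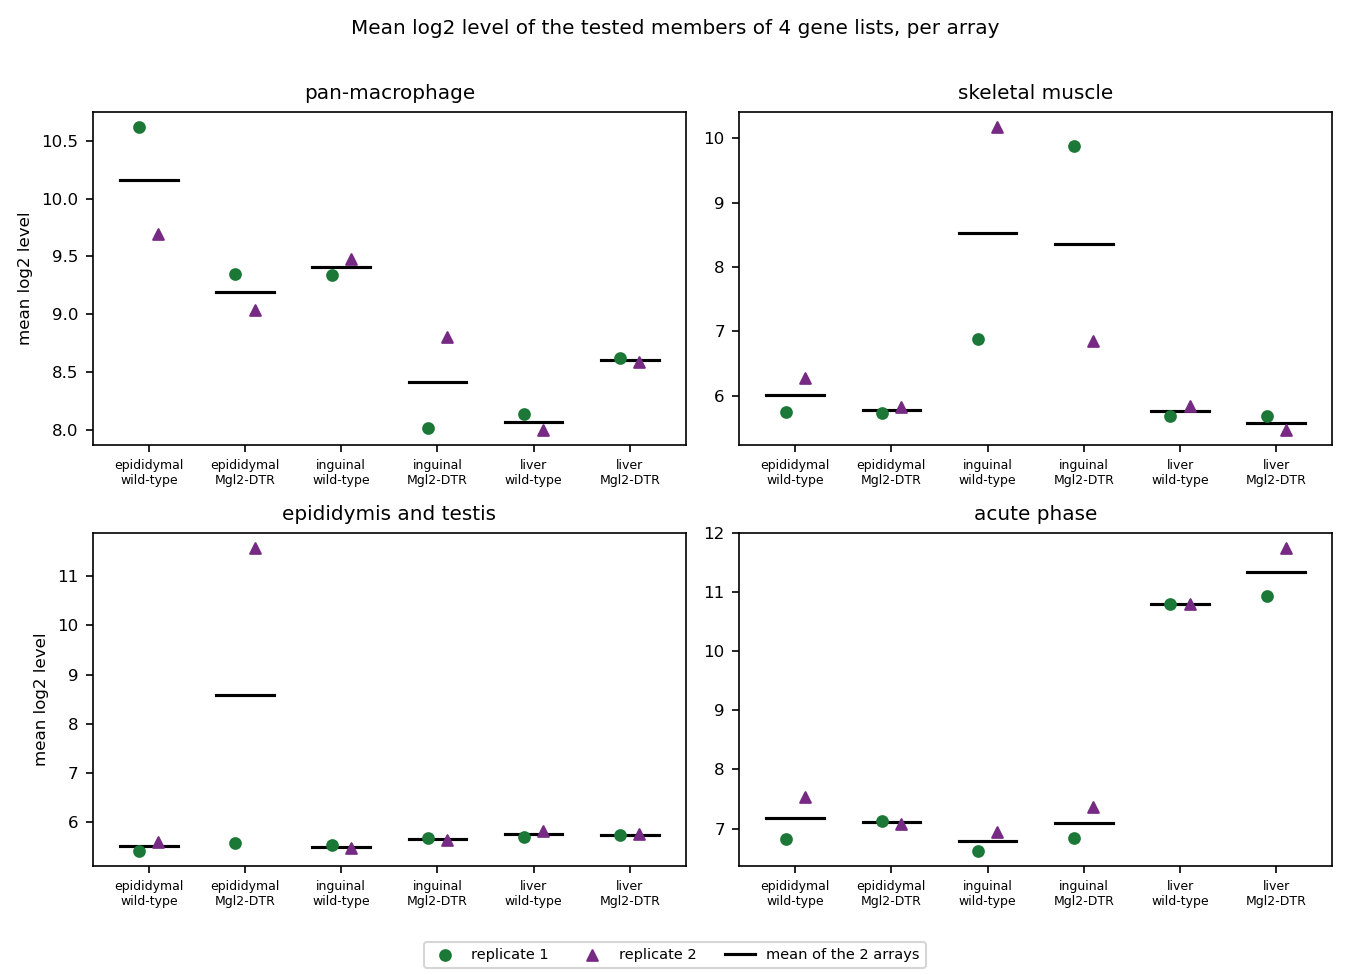
Mean log2 level (y axis) over the tested genes of the pan-macrophage, skeletal muscle, epididymis and testis, and acute phase lists in each of the 6 groups (x axis), with green circles for replicate 1, purple triangles for replicate 2 and a black line for the mean of the 2 arrays. Epididymis and testis genes averaged 11.57 in 1 Mgl2-DTR array of epididymal fat, and muscle genes averaged 10.18 and 9.88 in 1 inguinal array of each genotype.

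In liver, the question was which hepatic genes differed when the CD301b-positive cells had been depleted. Mgl2 was low in both genotypes, at 4.31 ± 0.40 and 4.24 ± 0.17 (change 0.068, SE 0.24), and the sign of this difference turned without wild-type replicate 2 (-0.052) or Mgl2-DTR replicate 1 (-0.21). Retnla was low as well, with a change of -0.48 (SE 0.39). Cyp2b9, a cytochrome P450 more abundant in female liver, rose by 3.41 (SE 0.33; adjusted p = 0.011), and Slc22a26, an organic anion transporter, rose by 2.86 (SE 0.28; adjusted p = 0.011). Hsd3b5, a steroid-metabolising enzyme of male liver, fell by 4.28 (SE 0.56; adjusted p = 0.036), Serpina4-ps1 fell by 4.21 (SE 0.45; adjusted p = 0.0152), and Selenbp2 fell by 2.56 (SE 0.22; adjusted p = 0.0103). In all, 4 genes rose and 5 fell, the others being Cyp4a14, a fatty acid hydroxylase (1.88, SE 0.21), Cyp2c38 (1.28, SE 0.16), the liver transcription factor Onecut1 (-1.93, SE 0.25) and Cyp4a12b (-1.71, SE 0.22). Slc22a26 rose from 5.02 and Hsd3b5 fell to 5.29, both under the filter level. The call of Hsd3b5 was lost without either wild-type array (adjusted p = 0.204 and 0.290), and its change was -5.45 without Mgl2-DTR replicate 1 and -3.11 without Mgl2-DTR replicate 2.

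Several of these genes belong to the liver's sex-dimorphic programme, which growth hormone controls. Of its 16 tested genes, 1 rose and 3 fell over all genes, and adjusted over the list alone 1 rose and 8 fell. Cyp2b9 was the rise, and the falls included Hsd3b5, Selenbp2, Serpina1e (-2.20, SE 0.51) and the anion transporter Slco1a1 (-1.26, SE 0.28). The female-biased members Cyp2b13 (3.77 and 3.78 in wild-type, 3.78 and 3.89 in Mgl2-DTR livers), A1bg (4.49 and 4.09, then 4.05 and 4.90) and Sult3a1 (2.79 and 3.01, then 3.02 and 3.32) lay under the filter level in both genotypes and were not tested. The list had a camera adjusted p of 5.53e-11, and adjusted p = 0.302 with an estimated correlation. Its mean level was 9.93 and 9.92 in the wild-type arrays, 9.33 in Mgl2-DTR replicate 1 and 8.73 in Mgl2-DTR replicate 2. Of 14 genes of bile acid and sterol transport, 0 fell over all genes and 3 fell adjusted over the list alone, Slco1a1, Cyp8b1 (-1.03, SE 0.23) and Cyp7a1, the rate-limiting enzyme of bile acid synthesis (-0.88, SE 0.21). That list had a camera adjusted p of 0.00953 and adjusted p = 0.642 with an estimated correlation, and its call was lost without Mgl2-DTR replicate 2 (adjusted p = 0.172) or wild-type replicate 1 (adjusted p = 0.350). Cyp2b9, Cyp4a12b, Cyp4a14, Serpina1e and Serpina4-ps1 come from families of closely similar genes, whose RNA a probe can also read.

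In the Mgl2-DTR livers camera called several immune lists higher at the preset correlation and none with an estimated one. Of 17 interferon-stimulated genes, 16 were higher, 0 rose over all genes and 3 rose adjusted over the list alone, Zbp1, a nucleic acid sensor (1.30, SE 0.30), Gbp3 (1.18, SE 0.29) and Oasl2 (0.82, SE 0.22; camera adjusted p = 8.69e-08; adjusted p = 0.642 with an estimated correlation). Of 18 pan-macrophage genes, 0 passed over all genes, and adjusted over the list alone 2 rose, C1qb (0.70, SE 0.21) and C1qc (0.61, SE 0.17), and 1 fell, Cx3cr1 (-0.66, SE 0.13; camera adjusted p = 2.58e-05; adjusted p = 0.663 with an estimated correlation). Of 9 Kupffer cell genes, 0 rose over all genes and 3 rose adjusted over the list alone, the scavenger receptor Marco (1.30, SE 0.20), Vsig4 (0.89, SE 0.26) and Clec4f (0.54, SE 0.16; camera adjusted p = 9.37e-05; adjusted p = 0.302 with an estimated correlation). Of 7 MHC class II genes, 0 rose over all genes and 2 rose adjusted over the list alone, H2-Aa (0.77, SE 0.20) and H2-Ab1 (0.77, SE 0.20; camera adjusted p = 0.00382; adjusted p = 0.642 with an estimated correlation). Without Mgl2-DTR replicate 1 that list's adjusted p was 0.052. None of the 18 genes of resident, alternatively activated macrophages passed (Gas6 1.24, Folr2 0.65, Maf 0.35; camera adjusted p = 0.0385; adjusted p = 0.642 with an estimated correlation), and the call was lost whichever 1 of the 4 liver arrays was left out (adjusted p = 0.059 to 0.242) and without either Mgl2-DTR array of epididymal fat (adjusted p = 0.0823).

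All 20 acute phase genes were higher in the Mgl2-DTR livers, and none passed (Apcs 1.19, Orm2 1.14, Steap4 0.72). The list had a camera adjusted p of 0.000399, and adjusted p = 0.645 with an estimated correlation. Its mean was 11.75 in Mgl2-DTR replicate 2 and 10.80 to 10.94 in the other 3 livers, and its adjusted p was 0.693 without that array. Of 19 genes of the unfolded protein and integrated stress response, 0 rose over all genes and 1 rose adjusted over the list alone, Ddit3 (0.77, SE 0.18; camera adjusted p = 0.041; adjusted p = 0.862 with an estimated correlation), and without Mgl2-DTR replicate 2 the direction of the list's test turned, at a median of 0.027. Its adjusted p was 0.442 without wild-type replicate 1 and 0.0952 without either wild-type array of epididymal fat. None of 12 lipolysis and lipid droplet genes passed (G0s2 -0.95, Aqp7 -0.49, Plin5 -0.48; camera adjusted p = 0.0168; adjusted p = 0.642 with an estimated correlation), and the call was lost without wild-type replicate 1 (adjusted p = 0.102) or Mgl2-DTR replicate 1 (adjusted p = 0.0978). None of 20 respiratory chain genes passed (Ndufb5 -0.24, Cyc1 -0.24, Ndufv1 -0.20; camera adjusted p = 0.0385; adjusted p = 0.862 with an estimated correlation), and the call was lost without either wild-type array (adjusted p = 0.125 and 0.103) or Mgl2-DTR replicate 2 (adjusted p = 0.520). None of the 13 brown and beige adipocyte genes passed (Elovl3 -1.78, Cidea -0.49, Ppara -0.43; camera adjusted p = 0.041; adjusted p = 0.642 with an estimated correlation); in liver, Elovl3 also belongs to the sex-dimorphic list. The brown and beige call was lost whichever 1 of the 4 liver arrays was left out (adjusted p = 0.0567 to 0.225) and without either Mgl2-DTR array of epididymal fat (adjusted p = 0.0538). With no filter on dim genes the lipolysis, respiratory chain and brown and beige lists missed the threshold (adjusted p = 0.0629, 0.126 and 0.126).

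Genes that set the liver groups apart without passing over all genes were Abcd2 at 1.56, Slco1a4 at 1.56, Rdh16 at 1.33, Gadd45b at 0.97 and Cyp4a31 at 0.97 (adjusted p = 0.0583) on the higher side. On the lower side were Dio1 at -1.83, Ces3b at -1.43, AF357355 at -1.27, Dusp1 at -1.24 (adjusted p = 0.0823), Tmie at -0.97 and Cacng7 at -0.82. By limma 703 genes had an unadjusted p under 0.05, 402 of them higher, and the groups lay apart for 34.4% of genes against 33.3% by chance. With the replicate block only Cyp2b9 and Selenbp2 of the 9 calls stayed past the threshold, and Slc22a26, Hsd3b5, Serpina4-ps1 and the rest were lost. The 9 calls became 3 without Mgl2-DTR replicate 2, 14 without Mgl2-DTR replicate 1, and 5 without wild-type replicate 2 or any 1 wild-type array of either fat depot. They became 6 without the 2 epididymal arrays that stood apart, 1 without the 2 muscle-bearing inguinal arrays, 5 with the muscle covariate, and 0 when all probes were tested (2872 at an unadjusted p under 0.05). Of the 9, only Cyp2b9 held whichever 1 of the 4 liver arrays was left out, and Cyp2c38 was lost each time (adjusted p = 0.0903 to 0.325). Selenbp2 and Serpina4-ps1 were lost without Mgl2-DTR replicate 2 (0.0679 and 0.220), Slc22a26 without wild-type replicate 2 (0.0984), Onecut1 without either replicate 2 (0.144 and 0.325), Cyp4a12b without either wild-type array or Mgl2-DTR replicate 2 (0.176 to 0.325), and Cyp4a14 without wild-type replicate 1 or either Mgl2-DTR array (0.0543 to 0.220).

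**Figure D3:**
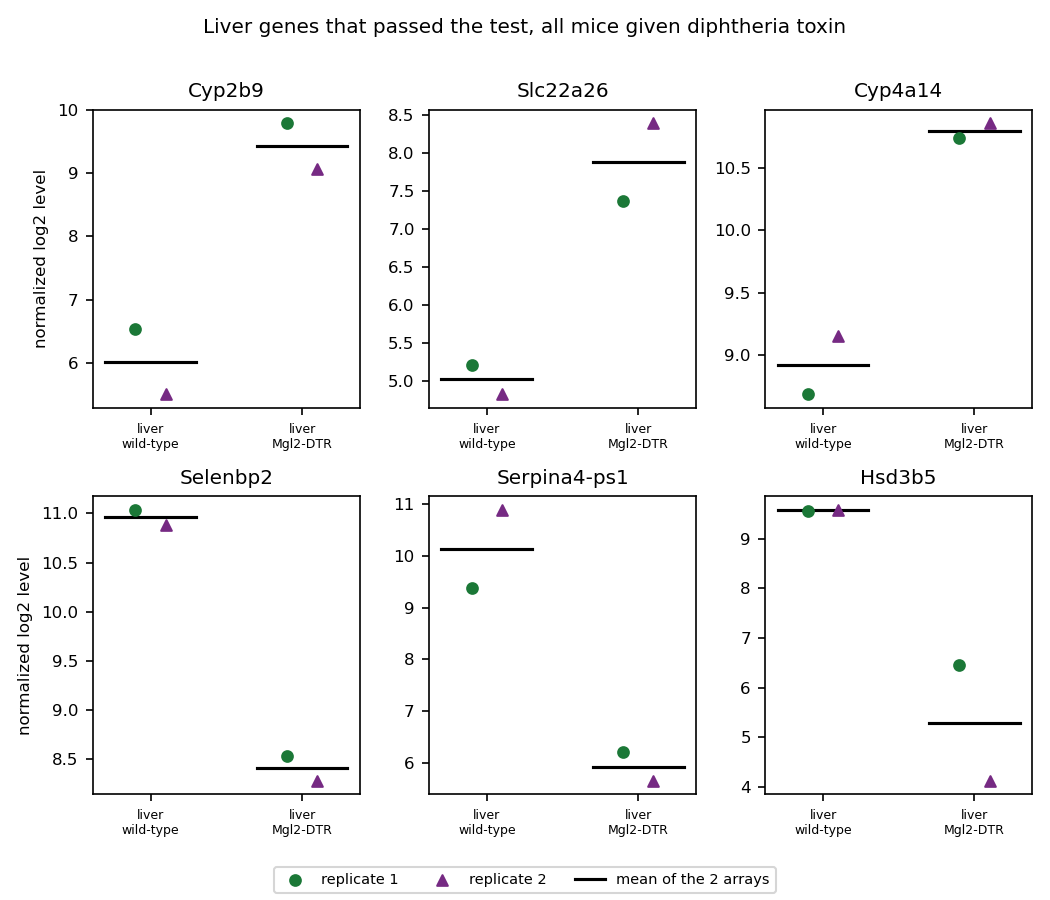
Normalized log2 level (y axis) of Cyp2b9, Slc22a26, Cyp4a14, Selenbp2, Serpina4-ps1 and Hsd3b5 in wild-type and Mgl2-DTR liver (x axis), with green circles for replicate 1, purple triangles for replicate 2 and a black line for the mean of the 2 arrays. Cyp2b9 averaged 6.01 in wild-type and 9.43 in Mgl2-DTR liver, and Hsd3b5 averaged 9.57 and 5.29.

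The effects were then compared between tissues. The sources used here do not say whether the 3 tissues were taken from the same mice, and these comparisons treat all arrays as independent. With genotype and number as a random block, 0 genes were called between depots, 30 between liver and fat, and 9 in the average, the same counts as without it. For the depots of wild-type mice 195 were called. All 24 genes that fell in inguinal fat were below 0 in epididymal fat too, 22 of them at an unadjusted p under 0.05, and 6 were below 0 in liver. The 4 genes that fell in epididymal fat were all among the 24 that fell in inguinal fat. Independent lists of these sizes would share 0.00755. These lists are not independent, since both tests use the same variance estimate of a gene, so that number is no measure of chance here. Across genes, which are not independent replicates, the changes of both depots had a Pearson's r of 0.390 and a Spearman's rho of 0.322. No gene differed between depots by limma's test of the difference (0 of 12710; smallest adjusted p = 0.341), with 364 at an unadjusted p under 0.05. The 2 depots' difference called 104 genes without epididymal wild-type replicate 2, 123 without epididymal Mgl2-DTR replicate 1, 2 without inguinal wild-type replicate 1, 1 without epididymal wild-type replicate 1, and 2 without both epididymal arrays that stood apart. Adjusted over the list alone, the inguinal change was lower than the epididymal change for 3 resident macrophage genes, Ccl8 (-1.82, SE 0.42), Cd209g (-1.65, SE 0.44) and Folr2 (-1.24, SE 0.34). Ccl8 and Cd209g started lower in epididymal fat, at 6.43 and 6.45 in wild-type mice against 9.01 and 8.49 in inguinal fat, and ended under the filter level, so that the floor limits their differences. The camera adjusted p of the resident macrophage list for that difference was 4.64e-06, and adjusted p = 0.590 with an estimated correlation.

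The change in liver minus the mean change of both depots passed for 30 genes, 23 above 0 and 7 below, a balance that turned without epididymal Mgl2-DTR replicate 1. In both genotypes, 6 of them lay under the filter level in liver, among them Mgl2, Retnla, Cd209g, Ccl8 and Fcrls, where no fall could be read, and 7 lay under it in both depots, among them Serpina4-ps1, Cyp2b9 and Slc22a26. The other 17 included Folr2, Selenbp2, C1qa, C1qb, C1qc, H2-Aa, H2-Ab1 and H2-Eb1. Mgl2 (3.03, SE 0.30; adjusted p = 0.0107), Retnla (3.61, SE 0.48; adjusted p = 0.0202), Cd209g (3.69, SE 0.38; adjusted p = 0.0107) and Folr2 (2.47, SE 0.30; adjusted p = 0.0127) were on the positive side, and Serpina4-ps1 (-4.12, SE 0.55; adjusted p = 0.0202) and Selenbp2 (-2.37, SE 0.27; adjusted p = 0.0127) on the negative side. Of the 18 resident macrophage genes, 14 were above 0 adjusted over the list alone, with a median of 1.28, a camera adjusted p of 2.47e-20 and adjusted p = 0.0335 with an estimated correlation. The 30 calls became 0 without liver wild-type replicate 2 (825 at an unadjusted p under 0.05), 6 without liver Mgl2-DTR replicate 2, 12 without liver wild-type replicate 1, 15 without liver Mgl2-DTR replicate 1, and 18 and 17 without inguinal wild-type replicate 1 and 2. They became 244 without epididymal wild-type replicate 2, 134 without epididymal Mgl2-DTR replicate 1, 4 when all probes were tested, and 0 without the 2 muscle-bearing arrays (638 at an unadjusted p under 0.05).

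Averaged over the 3 tissues, 9 genes fell and none rose, although an average can rest on fat or liver alone. Retnla fell by 2.88 (SE 0.23; adjusted p = 0.00163), Cd209g by 2.23, Mgl2 by 1.95, Ccl8 by 1.66, Lyz1 by 1.63, Fcrls by 1.31, Selenbp2 by 0.98 (adjusted p = 0.0381) and C1qa by 0.91. In liver alone, Mgl2, Cd209g, Fcrls and C1qa changed by 0.068, 0.23, 0.29 and 0.32. Retnla, Ccl8 and Lyz1 changed there by -0.48, -0.054 and -0.099. Mgl2, Retnla, Cd209g, Fcrls and Ccl8 lay under the filter level in liver in both genotypes. Selenbp2 changed by -2.56 in liver, but by -0.27 and -0.11 in epididymal and inguinal fat. Of 17 interferon-stimulated genes, 16 were above 0 in the average, 0 rose over all genes and 10 rose adjusted over the list alone, with a median of 0.50, a camera adjusted p of 2.14e-11 and adjusted p = 0.399 with an estimated correlation. The 9 calls became 297 without epididymal wild-type replicate 2, 146 without epididymal Mgl2-DTR replicate 1, 22 without epididymal wild-type replicate 1, 17 without inguinal Mgl2-DTR replicate 2, and 5 without epididymal Mgl2-DTR replicate 2, liver wild-type replicate 2 or liver Mgl2-DTR replicate 2.

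As a scale for these changes, inguinal and epididymal fat of wild-type mice differed in 190 genes, 106 higher and 84 lower in inguinal fat. That balance turned toward lower genes when epididymal wild-type replicate 1 or replicate 2 was left out. Higher in inguinal fat were Tbx15 (3.45, SE 0.15; adjusted p = 1.75e-05) and Hoxc10 (2.89, SE 0.28), which are transcription factors of body position, and Cidea (3.76, SE 0.19) and Cox8b (3.56, SE 0.20) of brown and beige adipocytes. Mmp3 (4.01), Il1r2 (3.96), Pon1 (3.18) and Cyp2f2 (2.67) were higher as well. Lower in inguinal fat were Upk1b (-4.68, SE 0.32) and Upk3b (-4.22, SE 0.30), genes of the mesothelium that covers the epididymal depot, together with Lrrn4 (-3.12, SE 0.30). Col6a5 (-5.21), Pkhd1l1 (-4.07), Tm4sf19 (-3.56), Atp6v0d2 (-3.29) and Alox15 (-3.13) were lower too. The 190 calls became 1445 without epididymal wild-type replicate 2, 77 without inguinal wild-type replicate 1 and 73 without inguinal wild-type replicate 2.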

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

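All tests of explanations below were chosen after the result was seen, except the rise of the second list of epididymis genes in the array itself, the sex-linked transcripts and the other splits of the samples. Each interval below is a bootstrap over the genes of a list, with the arrays held fixed. It holds no spread between mice, and it takes genes as independent although genes of a list can move together.

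The change in liver differed from the mean change of both fat depots, by limma's test of the difference, for 14 named genes. The difference was 3.69 for Cd209g, 3.61 for Retnla, 3.03 for Mgl2, 2.47 for Folr2, 2.42 for Aoah and 2.41 for Ccl8, all of which fell in inguinal fat. It was 3.62 for Cyp2b9 and 2.87 for Slc22a26, which rose in liver, and -4.12 for Serpina4-ps1, -2.37 for Selenbp2 and -2.08 for Onecut1, which fell in liver. Bmp3 had a difference of -1.85 (epididymal 0.88, inguinal 1.005, liver -0.91), Gal3st2b of -1.52 and Cx3cr1 of -0.99, and none of these 3 was called over all genes in a single tissue. In both genotypes Mgl2, Retnla, Cd209g, Ccl8 and Bmp3 lay under the filter level of 5.71 in liver, and Cyp2b9, Slc22a26, Serpina4-ps1 and Onecut1 lay under it in both depots, so these differences do not by themselves show a different response. The 30 calls of this comparison became 0 without liver wild-type replicate 2.

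The genes of epididymis and testis were high in epididymal fat of Mgl2-DTR replicate 2 alone, and 100 tested genes were higher there by over 2 than in each other epididymal array. A response of the fat to the depletion is argued against by Mgl2-DTR replicate 1, where a second list of 20 epididymis genes had a median change of 0.0257 (95% bootstrap interval -0.0739 to 0.0674). A candidate explanation is a piece of epididymal duct in that sample: the second list was raised by a median of 5.73 (interval 4.35 to 6.47) and 19 of its 20 genes by over 1. The most abundant there were Gpx5 at 12.74 (3.59 in the other 3 arrays), Wfdc10 at 12.30, Lcn12 at 11.76 and Spint4 at 11.60, while 2 of the 20 exceeded the filter level in the other 3 arrays and 0 were in another list. No sort or gate that would remove such tissue is described.

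The pan-macrophage list was lower in both fat depots by camera at the preset correlation only, with adjusted p = 0.503 in epididymal and adjusted p = 0.260 in inguinal fat with an estimated correlation, and 0 and 3 of its 18 genes passed over all genes. In inguinal fat, a dilution that lowers endothelial, progenitor and macrophage RNA alike is argued against. Endothelial and progenitor genes had a median 1.16 above that of pan-macrophage genes (interval 0.650 to 1.67). Added tissue that itself carries endothelial or progenitor RNA is not covered by this test. The endothelial mean was 8.78 in Mgl2-DTR replicate 1 and 8.24 to 8.38 in the other inguinal arrays. The progenitor mean was 9.79 to 9.85 in all of them. Muscle genes marked 1 array of each genotype, with means of 10.18 and 6.87 in wild-type and 9.88 and 6.84 in Mgl2-DTR fat. With that balance, a muscle effect alike in both genotypes is argued against as the source of this fall. The pan-macrophage mean was 9.48 with muscle and 9.34 without in wild-type fat, and 8.02 and 8.81 in Mgl2-DTR fat. Muscle acting in the Mgl2-DTR array alone cannot be told apart from the depletion as a source of part of the fall. The pan-macrophage median was -1.06 with all arrays. It was -0.52 (interval -1.18 to 0.0181) without both muscle-bearing arrays, on 1 array per genotype. In epididymal fat, a macrophage-rich wild-type array and the depletion cannot be told apart for this list: without wild-type replicate 1 the pan-macrophage median was -0.45 (interval -0.838 to -0.258), on a single remaining wild-type array. That the depletion may remove resident macrophages as well as CD301b-positive cells, or lower their gene expression, stays a hypothesis that these bulk values do not separate.

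Male-biased genes were lower in the Mgl2-DTR livers, with a median of -1.22 over 12 members, all below 0. Female mice are argued against, since no array stood apart. Over the 12 arrays the mean of the Y-linked transcripts lay between 7.59 and 7.94 and Xist between 3.46 and 4.28, at least 3.59 lower in each. Exchanged genotype labels between male samples would not show in these transcripts. In liver Mgl2 lay under the filter level in both genotypes, so it cannot check the labels there. An acute phase response in 1 mouse is argued against as the whole cause, since without Mgl2-DTR replicate 2 the median was -0.738 (interval -1.95 to -0.312). That value rests on a single Mgl2-DTR array. Lower food intake stays a possible explanation: the median of the fatty acid oxidation and PPARA target list was 0.000214 (interval -0.0886 to 0.143), with 10 members above and 10 below 0, which decides nothing. Among the members above 0 was Cyp4a14, a called rise in liver (1.88, SE 0.21). An effect of the depletion on growth hormone signalling, or of the genotype without toxin, was not tested.

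For the average over the 3 tissues, chance was kept as an explanation by the rule set beforehand, which keeps it at a share of 0.05 or more of splits as large. Beyond that rule the other splits do not settle the question, since a structure other than genotype fills them. Of 100 splits within tissues, drawn from 108 possible, 38 called at least as many genes as the real one, the real one included, with 9 in the real split and 38 in the highest other. Of the 37 others as large, 34 put both muscle-bearing inguinal arrays on the same side, as no further split did, and these called at least 21 genes each, while the other 3 grouped the arrays of both fat depots by genotype. Splits that did neither called at most 2 genes, a grouping made after the counts were seen. The split by replicate number called 2 genes.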

How the results depend on the processing

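The tests without the muscle-bearing arrays, with the muscle covariate, without the 2 epididymal arrays that stood apart and with a crossed block were chosen after the results were seen. The called genes named in the 3 tissues kept their direction in each of their 13 alternatives. In inguinal fat Mgl2, Retnla, Cd209g, Ccl8, Fcrls and C1qc, and in liver Cyp2b9, also stayed past the threshold when any 1 array of that tissue was left out. Clec10a (adjusted p = 0.0868 to 0.246), Ms4a14 (0.107 to 0.358) and Slc40a1 (0.0917 to 0.194) in inguinal fat, and Cyp2c38 in liver (0.0903 to 0.325), lost their call whichever 1 array of the tissue was left out. Array signal limits genes near the dim end, and in counts below the cause was not tested unless fewer arrays or more features explain it by construction.

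The 4 epididymal calls became 1 with no filter, with all probes, with quantile normalization again, with array weights, with the fat arrays alone, without the muscle-bearing arrays and with the muscle covariate, where Mgl2 was the gene kept. They became 0 with the stricter filter (484 at an unadjusted p under 0.05 by limma) or the epididymal arrays alone (285), and 7 at an adjusted p under 0.10. Leaving out 1 array gave 0 (Mgl2-DTR replicate 2, 454 at an unadjusted p under 0.05) to 763 (wild-type replicate 2). The 25 inguinal calls became 55 with array weights, 44 without the 2 epididymal arrays, 9 with the fat arrays alone, 4 with the inguinal arrays alone and 0 without the muscle-bearing arrays (479 at an unadjusted p under 0.05). Leaving out 1 array gave 6 (inguinal wild-type replicate 2) to 38 (either epididymal wild-type array). The 9 liver calls became 0 with all probes (2872 at an unadjusted p under 0.05), 16 at an adjusted p under 0.10, 1 without the muscle-bearing arrays and 5 with the muscle covariate. Leaving out 1 array gave 3 (liver Mgl2-DTR replicate 2) to 14 (liver Mgl2-DTR replicate 1). For the changes whose construction does not show it, the cause was not tested.

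The 9 calls of the average became 17 with quantile normalization or cyclic loess, 15 with trend and robust, 19 at an adjusted p under 0.10, 5 without the muscle-bearing arrays, and 5 to 297 (without epididymal wild-type replicate 2) when 1 array was left out. The 0 calls between depots (364 at an unadjusted p under 0.05 by limma) became 2 without the 2 epididymal arrays and 0 to 123 (without epididymal Mgl2-DTR replicate 1). The 30 calls between liver and fat became 4 with all probes, 0 without the muscle-bearing arrays (638 at an unadjusted p under 0.05), and 0 (without liver wild-type replicate 2, 825 at an unadjusted p under 0.05) to 244 (without epididymal wild-type replicate 2). The 190 depot calls became 125 with the stricter filter, 317 at an adjusted p under 0.10, 86 with the fat arrays alone, 34 without the muscle-bearing arrays, and 73 (without inguinal wild-type replicate 2) to 1445 (without epididymal wild-type replicate 2). The cause was not tested.

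The called lists of epididymal fat numbered 13, and 0 with an estimated correlation (4 at an unadjusted p under 0.05) and 1 by fry, with 12 to 22 when 1 array was left out (22 without epididymal wild-type replicate 1). Those of inguinal fat numbered 12, then 1 and 2, with 11 to 16. Those of liver numbered 12, then 0 (2 at an unadjusted p under 0.05) and 0, with 7 to 12 (7 without liver Mgl2-DTR replicate 2). Without epididymal wild-type replicate 1 the tests of lipid-associated macrophage (median -0.034), cell cycle (0.41) and endothelial genes (-0.027) turned direction, and without wild-type replicate 2 that of epididymal hepatocyte genes (0.061). When any 1 array was left out, these medians ranged from -1.36 to -0.034, -1.24 to 0.41, -0.035 to 0.51 and -1.04 to 0.061. Turned as well were the liver stress response list without Mgl2-DTR replicate 2 (0.027, up to 0.48 without Mgl2-DTR replicate 1) and the inguinal hepatocyte list without the muscle-bearing arrays (0.17). Without the 2 epididymal arrays, the lipid-associated (0.073), cell cycle (0.53), epithelial (-0.049) and epididymis (-0.045) lists turned. Mgl2 in liver turned to -0.052 without wild-type replicate 2 and to -0.21 without Mgl2-DTR replicate 1 (highest 0.35, without Mgl2-DTR replicate 2), and Myb in epididymal fat to -0.016 with its next probe. The cause was not tested.

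The sources used here do not say whether the samples are paired by number, and a weak correlation does not exclude it: r between the replicate differences of both genotypes, across genes, was 0.053 in epididymal fat, -0.12 in inguinal fat and 0.088 in liver. With the replicate block the calls were 1 in epididymal fat, 19 in inguinal fat (16 of them shared), 2 in liver, 5 in the average and 14 between liver and fat, and the cause was not tested. The crossed block in inguinal fat called 24 genes, 21 of them shared.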

Other observations

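The comparison of replicates by number was the 1 of the tests here that was chosen after the result was seen. Fkbp5, a chaperone that glucocorticoids induce, was higher in replicate 2 than in replicate 1 of all 6 groups, by 0.51 to 1.95, and the transcription factor Zbtb16 was higher by 0.57 to 2.60. The median difference over the 16 tested genes of the glucocorticoid and fasting response list was 0.83, 0.78 and 0.85 in wild-type epididymal fat, inguinal fat and liver, and 0.054, 0.23 and 0.28 in the Mgl2-DTR groups.

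Inflammatory genes of liver were mixed. Of 14 tested genes of monocytes and inflammatory cytokines, 0 rose over all genes and 3 rose adjusted over the list alone, Cxcl1, a neutrophil chemokine (2.23, SE 0.67), Ly6c2 of inflammatory monocytes (1.09, SE 0.30) and the chemokine Ccl5 (1.07, SE 0.30), while the list missed the threshold (camera adjusted p = 0.183). Cxcl1 stood at 10.04 in Mgl2-DTR replicate 2. In inguinal fat, the acute phase genes Saa3 and Lcn2 stood at 10.54 and 9.77 in Mgl2-DTR replicate 2, with changes of 2.18 and 2.05 that did not pass. Some metabolic lists gave small values: gluconeogenesis genes of liver had a median of -0.049 (camera adjusted p = 0.664) and insulin signalling genes of liver a median of 0.000113 (camera adjusted p = 0.925). The bile acid, lipolysis and respiratory chain lists of liver were called lower by camera at the preset correlation, as given above. A second probe of Erdr1 gave changes of 2.12, 2.04 and 1.71 in epididymal fat, inguinal fat and liver, where the first gave 1.22, 0.75 and 0.34.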
